A study of Homo sapiens with 4 samples.

How the data were processed

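Gene expression was measured by RNA-seq in 4 libraries of human cells, 2 with an empty vector and 2 with a U1 snRNA overexpression vector, 36 hours after the vector was given. Groups were taken from the genotype labels and replicate numbers from the sample titles. The treatment text given for the control samples names the overexpression vector as it does for the other group, so the labels differ on what the control cells received, and every comparison takes the genotype labels as right. Per the labels' protocols, total RNA was treated with DNase, and mRNA was fragmented and copied with random hexamers into adaptor-ligated libraries that were circularised before sequencing. No step that marks the strand is stated, so overlapping and antisense genes are reported as uncertain.

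The deposited table holds estimated counts per gene, not normalised, with 25283 rows, of which 17920 carry a symbol and 7363 an Ensembl identifier. Per the submitters' processing notes, the authors used Trim Galore, STAR, featureCounts and DESeq2 with the hg38 build, without stated versions or roles. Most values are not whole numbers: 1.99% of those above 0 lie within 0.01 of one, and how the fractions arose is not given in the sources used here. The smallest row sum is 4.00, and whether a filter set this is not given in the sources used here. If the fractions come from reads divided between genes, the values of paralogs and overlapping genes depend on that division. U1 snRNA, mitochondrial transcripts and transposable elements were not analysed here.

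The values were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: filterByExpr left 17317 genes, library sizes were scaled with TMM, and U1_OE was compared with control by the quasi-likelihood test with Benjamini-Hochberg adjustment and a threshold of 0.05. Per-library levels are TMM-scaled CPM. Errors beside CPM are SDs over 2 libraries and errors beside log2 fold changes are standard errors. Those of edgeR were worked back from the log2 fold change and the F statistic of the quasi-likelihood test. They therefore restate that test and are not the same measure as those of DESeq2. A gene at 0 in both libraries of a group was set against a floor of 3 counts per library, which covers counting error only. The totals of 16713505 to 19057423 counts limit precision mostly for genes of a few CPM, and the number of libraries limits it for the rest. The common dispersion was 0.0869.

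Before the data were examined, 36 gene lists were fixed, of which 2, the U1 snRNA genes and the mitochondrial transcripts, had no measured member. The 30 lists with at least 5 tested members were set against all other genes with camera (limma 3.58.1, preset correlation 0.01, and an estimated correlation as an alternative), two-sided, with Benjamini-Hochberg adjustment over lists. The 2 marker lists of microglia and blood cells and of neural crest, and those of glutamatergic and GABAergic neurons, had too few tested members. With an estimated correlation camera tests on the residual degrees of freedom, 2 for 4 libraries in 2 groups, so few lists could be called there. Adjustment over the list alone was also made, without adjustment across lists. Gene spans and coordinates come from GENCODE v29 on GRCh38, to which 82.4% of rows were matched, and 18S copies from a RefSeq gene table.

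The naming rule, also fixed then, took SNRNP70, SNRPA and SNRPC; the 8 largest rises and 8 largest falls among called genes with a mean of at least 50 counts and groups apart, without placeholder names or pseudogenes; up to 2 called members per list with the smallest p; and, with fewer than 5 called genes, the 10 genes with the smallest p as values. Because the main test called none, the parts of the rule that need called genes were applied to the DESeq2 calls, and members called by edgeR adjusted over a list alone were named as well. Both choices were made after the main result was seen. Not every gene that this would name is reported here.

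Alternatives chosen beforehand were RLE size factors, library size alone, no filter, a mean of at least 50 counts, DESeq2 1.42.0, limma-voom, a replicate block, a fold change of at least 2 and each library left out in turn. The likelihood ratio test and the alternatives of the DESeq2 count, of single DESeq2 values and of the Fisher tests were added after the results were seen. Where a library was left out, the lone library of its group was assumed to vary like the other group. Scaling moved the median log2 fold change of all tested genes little, from -0.01 with TMM to 0.01 with RLE and -0.04 with library size alone.

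The procedures were tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold among 17317. DESeq2 recovered 25% and 70%, limma-voom 7% and 45%, and the likelihood ratio test 26% and 71% with 60 false calls. In 5 draws without change the likelihood ratio test called 31 to 66 genes and limma-voom 0 to 1. In simulated counts with 1 list shifted 1.5-fold, camera called that list and 0 of 28 others. Genes were drawn independently there, so false calls of lists with correlated genes were not tested. In the data the estimated correlation of the cell cycle list was 0.749. Chi-square per degree of freedom between libraries was 24.1 or more, so no 2 libraries agreed within counting noise; this does not exclude repeat preparations of the same RNA. Tables and plots were made with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.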

Results

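RNA was sequenced from cells that the labels call neurons, derived from H1, an established human embryonic stem cell line, through neural progenitors and a maturation medium. The cells had received a lentiviral vector for 36 hours. One group of 2 libraries carried an empty vector (control) and the other group of 2 libraries carried a vector for overexpression of U1 snRNA (U1_OE), the RNA of the particle that recognises 5′ splice sites and restrains premature polyadenylation. The deposited estimated counts summed to 17061796 and 17636307 in the control libraries and to 16713505 and 19057423 in the U1_OE libraries, over 25283 genes. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which can be technical. The treatment text of the control samples names the overexpression vector too, so the grouping rests on the genotype labels and on the sample titles, which name the same groups. U1 snRNA itself, mitochondrial transcripts and transposable elements were not analysed here, so the level of the overexpressed RNA was not checked in any library.

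The transcripts that led the libraries were those of collagen-producing mesenchymal cells. COL1A1, the main chain of type I collagen, ranked 1 in each of the 4 libraries and took 2.92% and 3.93% of the counts in the control libraries and 4.03% and 3.97% in the U1_OE libraries. All 22 genes of a list of mesenchymal and fibroblast markers reached 10 CPM (counts scaled to a common library size) in every library, with a median of 683 to 1053 CPM. Most neuronal transcripts were lower. The list of pan-neuronal cytoskeleton and identity genes had a median of 5.34 to 7.39 CPM, and 17 of its 22 measured members reached 1 CPM and 8 reached 10 CPM in every library. Of the remaining neuronal markers, 3 of 16 glutamatergic markers were among the measured genes, and the GABAergic list had a median of 0.177 to 0.332 CPM. DCX, a microtubule protein of young neurons, had 0 and 0.111 CPM in the control libraries and 0 and 0.157 CPM in the U1_OE libraries. STMN2, a growth cone protein, had 0.294 and 0 CPM in the control libraries and 0.0616 and 0.0524 CPM in the U1_OE libraries.

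**Figure D1:**
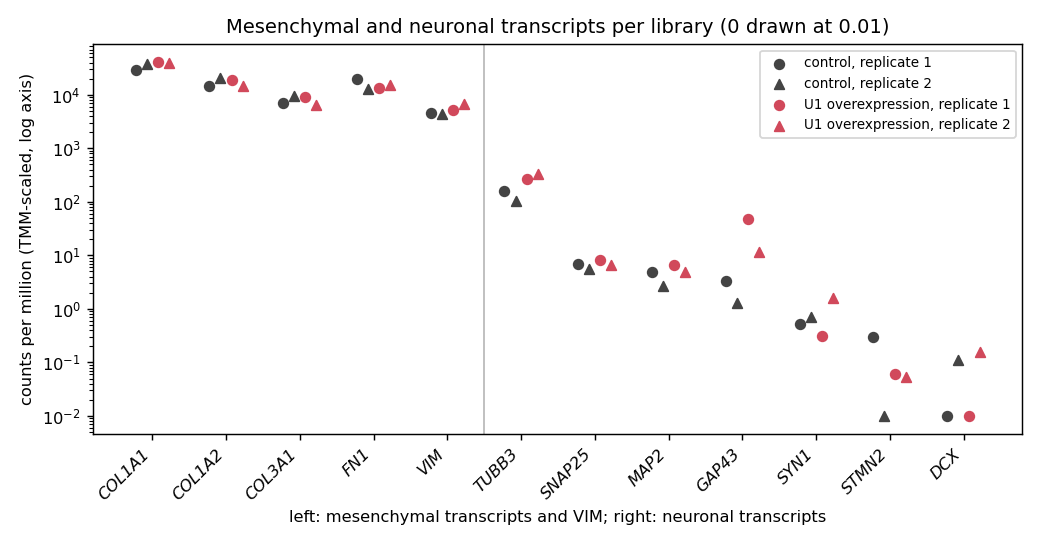
Level of 12 transcripts in each of the 4 libraries, in TMM-scaled CPM on a log axis; grey symbols are control and red symbols U1_OE libraries, circles replicate 1 and triangles replicate 2. COL1A1 lies near 29374 to 41457 CPM, TUBB3 at 104 to 338 CPM and STMN2 at 0.294 CPM or below.

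The first question was which genes differ between U1_OE and control cells. No gene passed the test chosen before the data were examined, so the values that follow for single genes are the 10 with the smallest unadjusted p and are not changes called by that test. L1CAM, a neural cell adhesion molecule, had 57.4 ± 0.161 CPM in control and 18.3 ± 2.41 CPM in U1_OE libraries (SD, n = 2). DDIT4, a stress-induced inhibitor of mTORC1, had 110.2 ± 12.6 and 38.3 ± 2.04 CPM, and ADA, adenosine deaminase, 133 ± 24.0 and 37.4 ± 3.89 CPM. FLT1, a receptor for vascular endothelial growth factor, had 3.27 ± 0.790 and 16.5 ± 0.291 CPM, and the metalloprotease gene ADAM19 23.1 ± 0.257 and 58.3 ± 0.296 CPM. NEAT1, the nuclear RNA that scaffolds paraspeckles, had 378 ± 37.2 and 159 ± 1.06 CPM.

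By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 17317 tested genes lay under an adjusted p of 0.05, 0 higher and 0 lower. The lowest adjusted p was 0.459, and 1572 genes had an unadjusted p under 0.05. In simulated counts of 17317 genes with the spread of these libraries, this test recovered 7% of 2-fold changes and 55% of 4-fold changes. The log2 fold changes by edgeR, with their standard errors, were -1.65 ± 0.15 for L1CAM (chromosome X, 153861514 to 153886174, minus strand), 1.33 ± 0.12 for ADAM19, -1.52 ± 0.15 for DDIT4 (chromosome 10, 72273920 to 72276036, plus strand), -1.83 ± 0.19 for ADA, 2.33 ± 0.25 for FLT1, -1.24 ± 0.14 for NEAT1 (chromosome 11, 65422774 to 65445540, plus strand), and -1.63 ± 0.20 for TM7SF2, a sterol reductase. ENSG00000270321, a gene with no symbol on chromosome 3, had -2.82 ± 0.32. IQCJ-SCHIP1 and the histone gene H4C11 had 0 counts in both control libraries, and U1_OE libraries had at least 42.4-fold and at least 34.3-fold more against a floor of 3 counts per library. IQCJ-SCHIP1 overlaps SCHIP1, which had 34.5 ± 9.47 and 33.6 ± 2.09 CPM, and H4C11 has near-identical copies, so reads of both can be shared with their neighbours or paralogs.

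DESeq2, which the submitters also list among their tools, had been chosen beforehand as a second tool and called 189 genes, 107 higher and 82 lower in U1_OE, of 17440 with an adjusted p. Of the 189, 32 had 0 counts in both libraries of a group, and 35 were named only by an Ensembl identifier. Such zeros can depend on how reads were divided between genes. limma-voom, also chosen beforehand, called 0, and edgeR's likelihood ratio test, added after the main result was seen, called 325. In 5 simulated draws with no changed gene, DESeq2 called 14 to 38 genes and the quasi-likelihood test 0 to 2, and in the simulation with changed genes DESeq2 made 47 false calls and the quasi-likelihood test 4. All 185 of the DESeq2 calls that edgeR also tested had an unadjusted edgeR p under 0.05 and the same direction. Both tools fit the same libraries, so this agreement is not separate support. Without control replicate 1, control replicate 2 or U1_OE replicate 2, DESeq2 called 55, 62 and 322 genes, of which 34, 42 and 101 were among the 189. The balance of directions also moved, to 42 higher and 13 lower without control replicate 1, and to 94 higher and 109 lower with a mean of at least 50 counts. The choice to name genes from the DESeq2 calls was made after the quasi-likelihood test had called none. Of the 35 genes so named, 9 stayed called without each library in turn, IQCJ-SCHIP1, H4C11, SCUBE3, ID3, ID1, CD44, ADA, MMP11 and DDIT4. Another 6, ECSCR, CILP, CASP1, H3C4, CTSB and SOX9, were called in none of these smaller fits, and 22, 19, 13 and 9 of the 35 were not called without control replicate 1, control replicate 2, U1_OE replicate 1 and U1_OE replicate 2. With the replicate block 14 of the 35 were not called, H4C11 among them (0.959), so 8 were called in all of these fits.

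Among the DESeq2 calls the largest rises by the naming rule included GAP43, a growth-associated protein of axons, at 2.28 ± 1.43 CPM in control and 29.2 ± 25.0 CPM in U1_OE libraries, with a log2 fold change of 3.69 ± 0.68 (SE; DESeq2 adjusted p = 4.63e-05). Without U1_OE replicate 1 it was 2.36 and not called (adjusted p = 0.272), and without control replicate 1 it was 4.53. ID3, an inhibitor of basic helix-loop-helix factors, rose from 25.5 ± 8.95 to 178 ± 89.7 CPM (DESeq2 adjusted p = 4.96e-10), and SCUBE3, a secreted glycoprotein, from 19.5 ± 3.21 to 137 ± 65.3 CPM (DESeq2 adjusted p = 9.54e-12). The log2 fold change of ID3 was 2.19 without U1_OE replicate 1 and that of SCUBE3 2.22 without U1_OE replicate 2, against 2.81 and 2.83 over all libraries. NTSR1, the neurotensin receptor, and ECSCR, an endothelial surface protein, rose by 4.59 ± 1.02 and 3.23 ± 0.73 on the log2 scale from control levels under 1 CPM. NTSR1 was 3.36 and not called without U1_OE replicate 2 (DESeq2 adjusted p = 0.766), nor called without control replicate 1 (0.0861) or 2 (0.114), and ECSCR was called in none of the fits with a library left out (0.0576 to 0.620). H4C15 had 0 counts in both control libraries, with 25.0 and 2.41 CPM in the U1_OE libraries, and its reads can be shared with other H4 genes. Falls named by the same rule were those of DBP and KLF9, transcription factors with circadian or hormone-driven expression, with log2 fold changes of -2.81 ± 0.68 and -2.24 ± 0.60 by DESeq2, and of KLRK1 and KLRC4, neighbouring receptor genes of lymphoid cells, with -2.57 ± 0.48 and -2.38 ± 0.69. KLRK1 and KLRC4 overlap a readthrough gene, so their reads can be counted for each other. CILP, MMP11 and TP53I11 fell by 2.18, 1.81 and 1.68 on the log2 scale by DESeq2, and CILP was -1.59 without control replicate 2. DBP, KLF9, KLRC4 and H4C15 kept their calls only without U1_OE replicate 2, where KLRC4 was -3.12. KLRK1 lost its call without control replicate 1 (0.0824) or 2 (0.354) and TP53I11 without control replicate 1 (0.0718).

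**Figure D2:**
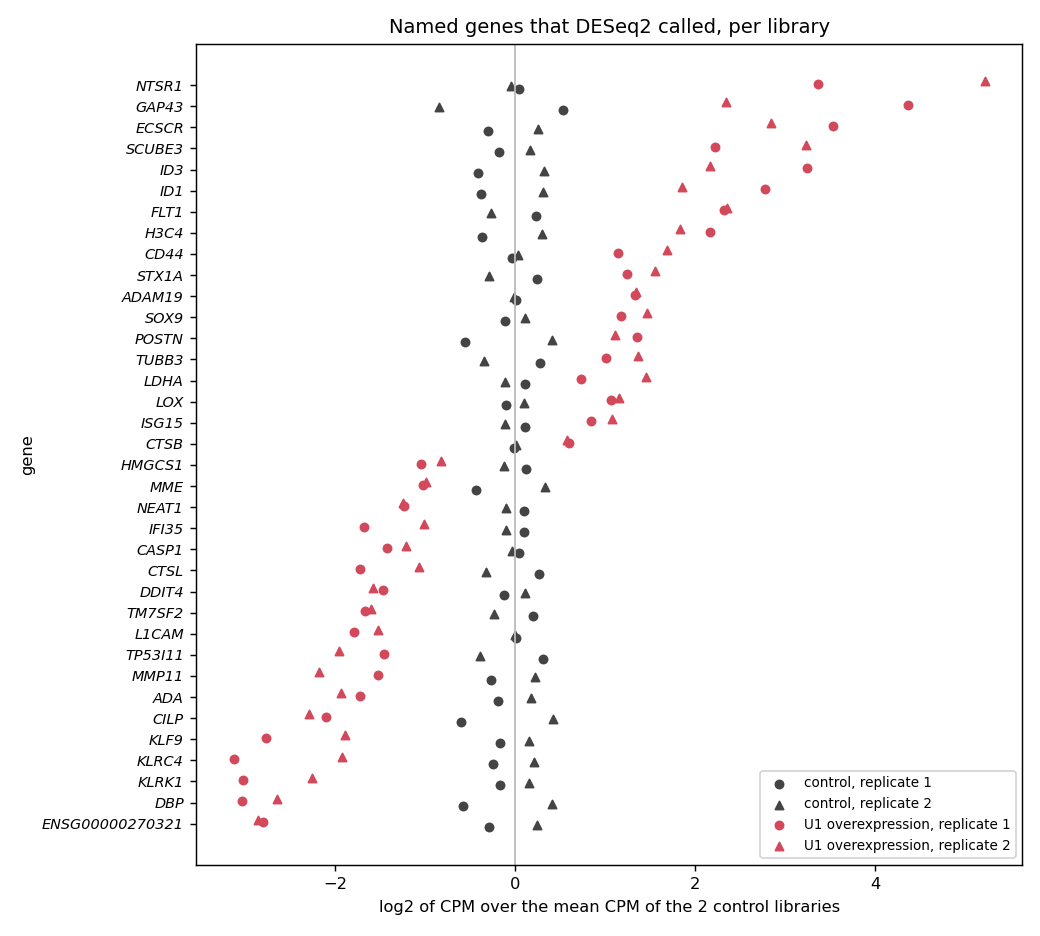
Level of each named gene that DESeq2 called, by whichever rule it was named, with counts in both groups, as log2 of its CPM over the mean of the control libraries; grey symbols are control and red symbols U1_OE libraries, circles replicate 1 and triangles replicate 2. GAP43 lies at 46.9 and 11.5 CPM in the U1_OE libraries, a wide spread within the group, while ADAM19 lies at 58.1 and 58.6 CPM.

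The genes of the U1 particle and of the machinery it acts on showed no called change. SNRNP70, SNRPA and SNRPC, the U1-specific proteins, had edgeR log2 fold changes of -0.03 ± 0.14, 0.13 ± 0.13 and 0.10 ± 0.14. Of the 19 genes listed as U1 particle proteins or associated factors, 23 cleavage and polyadenylation factors and 35 tested splicing regulators, 0 were called by edgeR or by DESeq2. Tested against all other genes with camera, these lists had adjusted p of 0.651, 0.704 and 0.202 (adjusted p = 0.846, 0.857 and 0.829 with an estimated correlation).

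Few members of the neuronal lists were called. DESeq2 called 1.08% of all genes with an adjusted p. Of 18 tested pan-neuronal genes it called a larger share, 2 higher and 1 lower. Of these, the call was lost for GAP43 without U1_OE replicate 1, for TUBB3 without control replicate 2 (0.363) and for L1CAM without control replicate 1 (0.0517). Adjusted over the list alone, edgeR's quasi-likelihood test called 3, which were L1CAM, lower in U1_OE, and TUBB3 and GAP43, higher. TUBB3, a neuronal beta-tubulin, had 132 ± 39.4 CPM in control and 301 ± 52.5 CPM in U1_OE libraries. Among 18 tested presynaptic genes, the syntaxin STX1A was among those called by edgeR adjusted over the list alone, against 0 called over all genes tested. Its edgeR log2 fold change was 1.41 ± 0.24. DESeq2 called STX1A at 1.42 ± 0.29 (adjusted p = 0.000385). Its DESeq2 log2 fold change was 1.72 without control replicate 1 and 1.17 without control replicate 2, where the call was lost. No postsynaptic gene or voltage-gated ion channel was called by edgeR or DESeq2, and of 30 genes of amyloid and tau processing 1 fell by DESeq2, the membrane protease gene MME, with -0.99 ± 0.26. Without control replicate 2 MME was -0.57 and far from a call (adjusted p = 1.00), and it was not called with the replicate block either (0.0856). The camera adjusted p of these 5 lists were 0.556, 0.202, 0.310, 0.194 and 0.240 (adjusted p = 0.825, 0.714, 0.788, 0.714 and 0.678 with an estimated correlation).

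Markers of mesenchymal, progenitor, astrocyte and endothelial cells were higher in U1_OE libraries by camera with a preset correlation of 0.01, and in none of these lists was the call kept with an estimated correlation. The camera adjusted p were 6.76e-06 for mesenchymal, 7.66e-05 for progenitor, 0.00420 for astrocyte and 7.66e-05 for endothelial markers. Each became adjusted p = 0.678 with an estimated correlation. For progenitor markers the estimate was 0.00967, close to the preset value, yet the unadjusted camera p moved from 9.13e-06 to 0.0471. That setting tests on 2 residual degrees of freedom, so the lost calls do not decide whether these lists differ. Of 22 mesenchymal genes 19 had a positive log2 fold change, 3 rose by DESeq2, and LOX, the collagen cross-linking enzyme, rose from 381 ± 36.5 to 820 ± 36.9 CPM (DESeq2 adjusted p = 7.25e-09), with POSTN, a matrix protein, at 1.25 ± 0.31. LOX was not called without control replicate 1 (0.0729), and POSTN was called only without control replicate 2. The progenitor list held 13 tested genes, 8 with a positive and 5 with a negative log2 fold change, of which 3 rose by DESeq2 and 6 were called by edgeR adjusted over the list alone, SOX9, ID3, ID1, HES1, NOTCH1 and NES. SOX2 and PAX6, transcription factors of neural progenitors, had lower levels without a call, at 1.17 and 0.481 CPM and at 16.6 and 8.96 CPM in control and U1_OE libraries. ID1 rose from 47.3 ± 15.6 to 248 ± 108 CPM by DESeq2, and SOX9, which is also in the astrocyte list, from 7.74 ± 0.867 to 19.4 ± 2.73 CPM. In the astrocyte list 8 of 10 tested genes were positive, and CD44, a hyaluronan receptor that mesenchymal cells also express, rose from 85.3 ± 2.56 to 232 ± 61.5 CPM by DESeq2. In the endothelial list 4 of 5 tested genes were positive, and FLT1 and TEK were called by edgeR adjusted over the list alone, whereas KDR had 0.823 and 0.311 CPM. The libraries of a group did not agree on 2 of these lists: median levels over the measured astrocyte markers were 1.82 and 5.20 CPM in the control and 11.2 and 2.25 CPM in the U1_OE libraries, and over the endothelial markers 0.412 and 0.332 against 0.677 and 0.315 CPM. The progenitor call was lost without control replicate 1 (adjusted p = 0.108) and the astrocyte call without control replicate 1 (0.0807) or U1_OE replicate 1 (0.292).

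Genes of cholesterol synthesis were lower in U1_OE libraries by camera with a preset correlation (adjusted p of 1.29e-05), a call that was lost with an estimated one (adjusted p = 0.678 with an estimated correlation). Of 24 tested members 21 had a negative log2 fold change and 0 were called by edgeR over all genes. DESeq2 called 2: TM7SF2 and HMGCS1, which encode a sterol reductase and an early synthase of the pathway, fell from 37.4 ± 7.90 to 12.04 ± 0.393 CPM and from 359 ± 43.6 to 188 ± 20.5 CPM. Both were also called by edgeR adjusted over the list alone. DESeq2 did not call TM7SF2 without control replicate 1 (0.449), nor HMGCS1 without control replicate 1 (0.611) or 2 (0.111) or with the replicate block (0.0939). Genes of NF-kappaB and cytokine response were lower by camera, with 17 of 19 members negative, 0 called by DESeq2 and an adjusted p of 0.000558 (adjusted p = 0.678 with an estimated correlation), and the call was lost without control replicate 1 (0.108). The median over the measured NF-kappaB and cytokine genes was 18.5 and 12.7 CPM in the control libraries and 7.79 and 16.6 CPM in the U1_OE libraries. U1_OE replicate 2 thus lay between the control libraries. Cell cycle genes had 33 of 36 members negative and a camera adjusted p of 0.00102 (adjusted p = 0.825 with an estimated correlation). Their median was 5.77 and 9.90 CPM in the control libraries and 3.17 and 7.60 CPM in the U1_OE libraries, and the call was lost without control replicate 2 (0.476) or U1_OE replicate 1 (0.811).

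Heat shock genes, p53 targets and genes of hypoxia and glycolysis were higher by camera with a preset correlation, and none of these calls was kept with an estimated one. All 19 heat shock genes had a positive log2 fold change, with a median of 0.18 and an adjusted p of 0.000437 (adjusted p = 0.678 with an estimated correlation). Their median level was 110.5 and 89.0 CPM in the control libraries and 108.3 and 110.5 CPM in the U1_OE libraries, so control replicate 2 alone stood apart. For 24 p53 targets the median was 0.17 with an adjusted p of 0.00452 (adjusted p = 0.678 with an estimated correlation), and 0 of the members of either list were called by edgeR or DESeq2. For 28 hypoxia and glycolysis genes the median was 0.28 with an adjusted p of 0.00511 (adjusted p = 0.738 with an estimated correlation), and LDHA, lactate dehydrogenase A, rose from 679 ± 74.9 to 1489 ± 515 CPM by DESeq2, a call lost without control replicate 1 (0.0616) or 2 (0.293). Without control replicate 2 these calls were lost, at adjusted p of 0.0893, 0.109 and 0.305, and the p53 and hypoxia calls were also lost without U1_OE replicate 1 (0.206) and U1_OE replicate 2 (0.479) respectively. In all, camera called 10 of 30 lists, 7 higher and 3 lower, and 0 with an estimated correlation. By Fisher's exact test, two-sided and added after the calls were seen, DESeq2 calls of either direction were more frequent than among other genes in 5 of 32 lists, with Benjamini-Hochberg adjusted p of 0.0145 for pan-neuronal, 0.00821 for progenitor, 0.0318 for astrocyte and 0.0177 for mesenchymal genes and 0.0318 for autophagy and lysosome. Each list held only 2 or 3 calls, and none of the 5 results was kept without each library in turn. The pan-neuronal result was lost without U1_OE replicate 1 (adjusted p of 0.0831), the progenitor result without U1_OE replicate 2 (0.0934) and the mesenchymal result without either (0.529 and 0.0577). The astrocyte result was kept only without U1_OE replicate 1 (0.0413) and that for autophagy and lysosome in none of these fits (0.319 to 1.00). With a mean of at least 50 counts 2 of the 5 were kept, and with the replicate block 3.

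**Figure D3:**
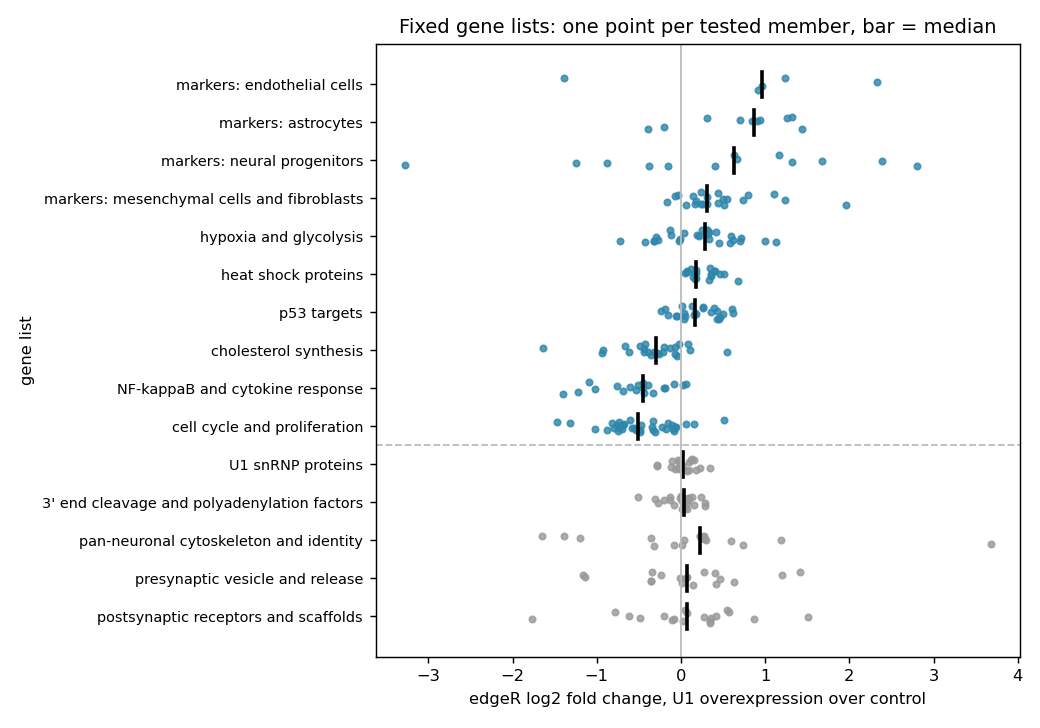
edgeR log2 fold change (U1_OE over control) of each tested member of the 10 lists called by camera, in blue, and of 5 lists of U1 and neuronal function that were not called, in grey; bars mark medians. The median of the cell cycle list is -0.51 and that of the list of U1 particle proteins and associated factors 0.02.

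The remaining lists were not called by camera over all 4 libraries, though single members passed a test. DDIT4, of the stress response list, was called by edgeR adjusted over the list alone and fell by DESeq2, as did CASP1, the inflammatory caspase, in the apoptosis list (log2 fold change -1.30 ± 0.36 by DESeq2). Within the interferon list the ubiquitin-like protein ISG15 rose and IFI35 fell by DESeq2, with 0.97 ± 0.22 and -1.29 ± 0.30. In the autophagy and lysosome list, the proteases CTSL and CTSB fell and rose by DESeq2, from 997 ± 282 to 388 ± 121 CPM and from 445 ± 5.62 to 667 ± 6.51 CPM. The CTSL call was lost without control replicate 1 (0.273), ISG15 was called only without U1_OE replicate 1 and IFI35 only without U1_OE replicate 2 among the fits with a library left out. The histone H3C4 rose by 2.02 ± 0.49 on the log2 scale by DESeq2. The lysosomal marker CD68 was called by edgeR adjusted over the microglia and blood list alone, at 0.74 ± 0.16. That list had only 4 tested genes, and over all genes the edgeR adjusted p of CD68 was 0.459. Of 47 ribosomal protein genes, 45 nuclear-encoded genes of oxidative phosphorylation and 31 genes of transposable element silencing, 0 were called by edgeR or DESeq2, and the same held for the immediate early, pluripotent, oligodendrocyte, epithelial, neural crest, glutamatergic and GABAergic lists.

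The last question was whether long genes, whose transcripts U1 protects from early polyadenylation, responded differently. Across the 15830 tested genes with an annotated span (91.4%), Spearman's rho of the edgeR log2 fold change with gene length was 0.0166, over genes that are not independent replicates. The longest genes, 3958 of at least 72.3 kb, had a median log2 fold change of 0.004 against -0.003 for the rest, with a camera p of 0.680 (p = 0.613 with an estimated correlation). Without control replicate 1 and without U1_OE replicate 1, rho was -0.0220 and 0.0494.

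Libraries of one group were not closer to each other than to the other group in every case. Spearman's correlation across genes was 0.973 between the control libraries, 0.960 between the U1_OE libraries and 0.953 to 0.969 between groups. The first principal component, with 43.4% of the variance, set U1_OE replicate 1 apart at 78.0, against -3.17 for U1_OE replicate 2 and -39.9 and -35.0 for the control libraries. The next component, with 30.7%, set U1_OE replicate 2 apart at -67.3, against 19.5 for U1_OE replicate 1 and 12.6 and 35.2 for the control libraries. Groups did not overlap for 41.8% of tested genes, where chance gives 33.3% on average for 2 libraries against 2. Genes vary together, so a share above 33.3% can arise without a difference between the groups.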

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

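The likelihood ratio test and the alternatives of the DESeq2 count, of single DESeq2 values and of the Fisher tests were chosen after the results were seen. The quasi-likelihood count of 0 was the same with other scalings, filters, limma-voom, the replicate block, a 2-fold minimum and each library left out (unadjusted p under 0.05 for 811 to 2632 genes and a lowest adjusted p of 0.0525, without U1_OE replicate 2, when a library was left out). DESeq2 called 189 genes (107 higher, 82 lower) and the likelihood ratio test 325 (137 higher, 188 lower). Their false calls in simulations without change, up to 38 and 66, show that these tools are more liberal at this number of libraries. A trend with GC content or transcript length is argued against as a source of the 170 DESeq2 calls that had both measures, and the rest of the difference stays open. Same-numbered libraries did not deviate together (correlation -0.0377), and with the replicate block edgeR called 0 genes and DESeq2 80, 73 of them among the 189. DESeq2 called 55 to 322 genes with a library left out and 203 with a mean of at least 50 counts (94 higher, 109 lower).

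Camera called 10 lists and 0 with an estimated correlation, a setting with 2 residual degrees of freedom at which few lists could be called. Without control replicate 1, control replicate 2, U1_OE replicate 1 and U1_OE replicate 2 it kept 7, 6, 7 and 9 of the 10. Cholesterol, mesenchymal and endothelial lists stayed called without any of the 4 libraries. Lists not called over all libraries changed direction when a library was left out, with adjusted p over these fits of 0.0306 to 0.969 for stress response, 0.206 to 0.682 for apoptosis, 0.0127 to 0.907 for interferon, 0.0210 to 0.682 for immediate early genes, 0.172 to 0.907 for ribosomal proteins, 0.108 to 0.854 for oxidative phosphorylation, 0.638 to 0.702 for transposable element silencing, 0.108 to 0.969 for epithelial markers and 0.0269 to 0.969 for histones; fewer libraries entered each fit, and the cause was not tested further. The log2 fold change of SNRNP70 ranged from -0.105 to 0.0725 and rho with gene length from -0.0220 to 0.0494, each crossing 0. Alternatives listed for transposable elements were not run, since these were not analysed here. With 7% of 2-fold changes recovered in simulation, many differences of that size were not detectable here.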

Other observations

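The gene families, the DESeq2 splits, the levels of collagen and neuronal genes, the simulated bound and the 18S genes were tests chosen after the results were seen; the GC and length test and the test on nuclear RNAs were written before, when the counts of 2 of the nuclear RNAs had been seen. Some families of related genes held DESeq2 calls, against 1.08% of all genes with an adjusted p; as the families were picked from the calls, no enrichment was tested. Of 14 tested genes with tubulin names, an antisense gene and a pseudogene included, 4 rose, TUBA1A, TUBA1B, TUBB6 and TUBB3, the last also in the pan-neuronal list, with TUBA1A at 1007 ± 97.1 CPM in control and 1752 ± 249 CPM in U1_OE libraries (SD, n = 2), while TUBB2A had 161 and 166 CPM. Of 3 metallothioneins, which bind zinc and copper, MT1E and MT1X rose, with log2 fold changes of 1.67 ± 0.48 and 1.99 ± 0.52 (SE), and MT2A was not called. MT1X was 1.11 and MT1E 1.21 without U1_OE replicate 1, neither called (adjusted p = 0.757 and 0.856 by DESeq2), and neither was called without control replicate 1 (0.364 and 0.868). Of 25 genes with integrin names, not all of them subunits, ITGA1 and ITGA5 rose.

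Of 6 tested genes of iron storage and transport, FTL, FTH1 and TFRC fell by DESeq2, and SLC11A2, SLC40A1 and TF were not called. FTL and FTH1, the ferritin chains that store iron, took 3.59% and 2.83% of the counts in the control libraries and 1.32% and 1.28% in the U1_OE libraries, with log2 fold changes of -1.14 ± 0.18 and -1.58 ± 0.22. TFRC, the transferrin receptor that brings iron in, had -1.45 ± 0.38. With a library left out, FTH1 stayed called in each fit, FTL was not called without control replicate 1 (DESeq2 adjusted p = 0.0955), and TFRC was called only without U1_OE replicate 1. The cathepsins went both ways, with CTSB higher and CTSH, CTSL and CTSO lower among 12 tested. SCD and SREBF1, genes of fatty acid synthesis and its control, rose by DESeq2 with 0.96 ± 0.23 and 0.96 ± 0.23. TUBA1B, TUBB6, ITGA1, CTSH, SCD and SREBF1 were each called in 1 of the 4 fits with a library left out, TUBA1A in 2 and CTSO in 0, while ITGA5 was called in 4. By edgeR's quasi-likelihood test none of these genes was called over all genes tested, and they were chosen after their values were seen.

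Collagen transcripts led all 4 libraries, and DCX and STMN2 lay near the floor, while TUBB3 did not, at 132 and 301 CPM in control and U1_OE libraries. The ratio of summed COL1A1, COL1A2 and COL3A1 to summed DCX, STMN2, GAP43 and MAP2 had a lowest value over the 4 libraries of 1299. It is built on genes that define the pattern and was chosen after their levels were seen, so it restates the pattern. Over all measured members of the lists fixed beforehand, the mesenchymal sum was 39.6 to 59.8 times the pan-neuronal sum. The same collagens made up much of that mesenchymal sum, 50855 of 81257 CPM in control replicate 1 and 69599 of 100239 CPM in U1_OE replicate 1. The list medians, which single genes do not set, were 683 to 1053 CPM for mesenchymal and 5.34 to 7.39 CPM for pan-neuronal genes. These medians argue against a small share of mesenchymal cells in a culture made mainly of neurons. Libraries from another culture under these labels may be a source, and stay open: at most 3 of the 16 glutamatergic markers reached 1 CPM in a library, and the overexpressed RNA was not analysed here. A culture that gave mostly mesenchymal cells during differentiation was not tested and stays open as well.

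DESeq2 called 189 genes where edgeR's quasi-likelihood test called 0. A trend with GC content or transcript length is argued against for the 170 called genes that had both measures. After both trends were removed, the called falls kept a share of 0.999 of their median log2 fold change and the called rises no less. The 189 calls were 4.97 times the most seen in 5 simulated draws without change, a bound from simulation that excludes nothing. The labelled grouping gave the most calls, 1 of 3 splits with as many as 189 and a highest other split of 77, but 3 splits are too few for a share under 0.05. The DESeq2 calls may include real responses to U1 snRNA, and which of them are cannot be told from 2 libraries per group.

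Genes antisense to 18S rRNA copies on chromosome 21, whose reads cannot be told from those of the rRNA if strand was not kept, took 1.38% and 1.04% of the counts in the control libraries and 0.569% and 0.475% in the U1_OE libraries, and NEAT1 fell by DESeq2 with -1.23 ± 0.17, though not without control replicate 1 (adjusted p = 0.0517). TALAM1 (-1.02 ± 0.26), called only without U1_OE replicate 2 when a library was left out (-0.72, adjusted p = 1.00, without control replicate 1), is antisense to MALAT1, which was not called (-0.66 ± 0.24 by DESeq2), and the same caution holds for these 2. A lower share of nuclear RNA as the whole cause is argued against by 13 other nuclear-retained RNAs. Their median log2 fold change was 0.10 (SD 0.29, from -0.36 to 0.67, 5 negative). MALAT1 was not among the 13, and with MALAT1 added the median was 0.07. The 6 genes of the pattern had a median of -1.22, and -1.24 without TALAM1. They were grouped because they were lower, so their distance from the 13 was built in and adds nothing. Less 18S rRNA carried into the U1_OE libraries could lower the 18S genes alone: all 4 were lower by edgeR's estimate, and their log2 fold changes spread over 1.03 through ENSG00000281383, at 1.52 to 8.12 CPM, while the 3 genes above 1000 CPM spread over 0.388; rRNA itself was not analysed here, so this and U1 overexpression stay open.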
